A study of Bifidobacterium breve UCC2003 with 2 samples.

How the data were processed

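Total RNA of Bifidobacterium breve UCC2003 carrying pNZ44-serR or pNZ44 was labelled with Cy3 and Cy5 and hybridised to 2 two-colour Agilent arrays on 1 slide, with the dyes swapped between them. Both strains were grown anaerobically in modified MRS medium with cysteine to an optical density of 0.5, per the labels. Spot values were extracted with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited scanner files hold, per the file headers, the mean raw intensity and the median local background intensity of each spot in both channels, and a processed intensity that is background-subtracted and dye-normalized. The deposited log10 ratios are, per the file headers, red (Cy5) over green (Cy3) processed signals. The authors' deposited value table holds the same log10 ratios of each array, with a largest difference of 0.00497, a median of 0 in both columns, and no turning of the swapped array. Which further centring the authors used, and which genes they called, is not given in the sources used here.

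Raw intensities were read with limma 3.58.1 in R 4.3.3 and corrected with normexp at an offset of 50. Red over green log2 ratios were normalized by loess within each array, with control spots at weight 0. Control spots and spots with an outlier flag were then left out. The flags took 1 of 10263 gene spots on array 1 and 11 on array 2; 0 and 2 gene spots were saturated and were kept. Spots of a probe were averaged, at most 2 per array, then the 3 probes of a gene, and the sign of array 2 was turned. In 74% of the genes the 3 probes start within 60 bases of each other, so they are not independent measurements. The array holds 1888 named features, of which 1843 carry a locus tag and were analysed, and 45 do not and stand apart. Negative control spots gave median intensities of 512.8 in Cy3 and 810.6 in Cy5 on array 1 and of 451.7 and 777.5 on array 2, against a local background of 37 to 44. Ratios of dim genes are therefore compressed. A gene counts as well above background in a strain on an array where at least 1 probe has the scanner's flag on at least 50% of its spots. Where that fails for one strain on both arrays, the ratio is given as a bound: the brighter strain's mean level against the dimmer strain's mean of, on each array, the higher of its own level and the lowest level of any spot well above background, after loess and Aquantile scaling. Such a bound refers to the mean of both arrays under this processing. It is a firm limit of that mean only where the brighter strain was well above background on both arrays. The number of arrays limits the precision.

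The labels do not say that the arrays used separate cultures, so the pair was counted as 1 replicate and called genes by a 3-fold mean ratio with the same sign on both arrays, the ratio given in the series' design text. limma (lmFit and eBayes, Benjamini-Hochberg over all genes, adjusted p of 0.05) was run beside it as a check of the repeatability between hybridisations. The methods' t-test is the regularised test named in the design text, here with a prior weight of 10 and a window of 101 genes; the settings the authors used are not given. It was applied to the same values, with their thresholds of p under 0.001 and a ratio above 3 or under 0.33. Gene lists were compared by the percentile of their median among 10000 random lists of the same size, matched on mean signal in 10 bins. These designs, the lists and the alternatives (background correction, normalization, the deposited ratios, the summary over probes, filters on dim and outlier spots, single arrays, thresholds and tests) were chosen before the data were examined, except where the text says otherwise.

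Of 23 gene lists, 3 were defined by locus tag: the serpin locus (Bbr_1319 and Bbr_1320), its neighbours (Bbr_1310 to Bbr_1329) and the exopolysaccharide cluster (Bbr_0430 to Bbr_0475), with the tags taken from knowledge of the strain and the study. The other 20, among them serR with serK, two-component systems, chaperones, proteases, ribosomal proteins and glycoside hydrolases, need a product or symbol and could not be used, since the files pair the locus tags with neither and 0 of 1888 array names matched the reference table, which describes another strain with 2016 genes. Genes are therefore named by locus tag, with no product and no genome position, and consecutive tags stand for neighbourhood. The rule for named genes was the serpin locus and then up to 15 genes with the largest mean in each direction. It left out genes not well above background in both strains on both arrays. Because the tags have no names, it was cut to the region Bbr_1310 to Bbr_1329 and, outside it, 2 genes in each direction. These were Bbr_1464 and Bbr_0249, and Bbr_1892 and Bbr_1893, picked by the size of their ratios. They had to pass 3-fold on each array. The filter on background was loosened to a signal well above background in at least 1 strain on at least 1 array. Of these, only Bbr_1464 passes the first filter, and Bbr_1318 in the region does not pass it. Naming Bbr_1318, Bbr_0249, Bbr_1892 and Bbr_1893 therefore departs from the rule. All other genes and regions outside the lists were singled out after their values were seen.

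The steps were tested on a simulated dye-swapped pair of this comparison, with 1843 genes of which 200 were changed, noise of 0.1 on the log2 scale and the negative controls as background. The 3-fold rule called 50% of 66 genes changed 6-fold, 25.4% of 67 changed 3.5-fold and 0 of 67 changed 2-fold. Among genes with a simulated signal of at least 500 over background it called 16 of 16 and 17 of 19 of the first 2 classes. It called 0 of 1643 unchanged genes, and limma's 162 calls held 6 unchanged genes. The simulated noise was independent between genes and held no runs of genes that differ between the arrays. Such runs gave some of the higher genes in the real data, so these counts of false calls do not cover them. No test of slide or scan day was possible, since both arrays share 1 slide.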

Results

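Transcription was compared between a pair of derivatives of Bifidobacterium breve UCC2003, a gut bacterium. One carried the serR gene on the plasmid pNZ44, an expression vector, and is called the serR strain. The other carried pNZ44 without an insert and is called the vector strain. According to the series title, the study asks how a two-component regulatory system, which as a class pairs a sensor kinase with a response regulator, controls the expression of serpin, a serine protease inhibitor. Total RNA from both strains, grown without oxygen in a rich medium to an optical density of 0.5, was hybridised together on 2 arrays. On array 1 the serR strain was labelled with Cy5 and on array 2 with Cy3. All ratios below are the serR strain over the vector strain, after the sign of the dye-swapped array had been turned. The arrays measured 1843 genes with a locus tag, each with 3 probes.

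The labels name 1 dye-swapped pair and no separate cultures, so the pair counts as 1 replicate of the comparison, and genes are called by size: a mean ratio of at least 3-fold with the same sign on both arrays. Each SD is the spread between the 2 arrays (n = 2 hybridisations). The p-values measure only that spread, which may be technical. On array 1, 24.5% of the spots were well above background in Cy5 and 22.1% in Cy3, and on array 2 these shares were 43.9% and 66.4%.

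Transcripts of the serpin locus were higher in the serR strain. Bbr_1319 gave a mean log2 ratio of 5.07 ± 0.22, and since the vector strain's signal was not well above background on either array, it was at least 14.7-fold higher (limma, Benjamini-Hochberg adjusted p = 1.1e-07). Bbr_1320 gave a log2 ratio of 1.71 ± 0.45, with an adjusted p of 0.00036 from limma, and its bound came to 1.12-fold. In the serR strain, Bbr_1320 was well above background on 1 of the 2 arrays. This bound therefore includes a serR level that was not well above background and is no firm lower limit. Without background correction the log2 ratio of Bbr_1320 was 0.93, under 3-fold. The higher value held for all 3 probes of each gene on both arrays. These probes overlap, so they are not independent measurements: they start at bases 224, 243 and 244 in Bbr_1319 and at 817, 818 and 819 in Bbr_1320. Both genes met the size rule and passed limma, over all genes and adjusted over the list alone, and the list median of 3.39 ± 0.33 was at percentile 100 of 10000 random gene pairs matched on signal. Those pairs were drawn without regard to gene order. Neighbouring genes tended to change together in these data, so the percentile may overstate how unusual 2 neighbours are. The sources used here do not give the locus tag of serR or serK, so the gene placed on the plasmid was not identified on the array.

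The gene with the largest measured higher ratio, Bbr_1318, lies next to the serpin locus in the order of locus tags. Its mean log2 ratio was 6.42 ± 0.49, with an adjusted p of 1.1e-07 from limma. The vector strain's signal was well above background on array 2, where the ratio was 6.07, and not on array 1, where it was 6.77. Whether Bbr_1318 or a neighbour is the gene carried on the plasmid was not determined, and the array does not separate transcripts of a plasmid copy from those of the chromosome. Bbr_1317, on the other side of Bbr_1318, gave 1.17 ± 0.34 (adjusted p = 0.0013, limma) with the same sign for all 3 probes, which also overlap. It was not well above background in the vector strain on either array, nor in the serR strain on 1 of the 2. Its bound came to a negative log2 value, -0.58, so no fold is given. Beyond these 4 genes, Bbr_1316 gave 0.07 ± 0.21 and did not pass limma. Bbr_1321 gave 0.44 ± 0.20, which passed limma adjusted over the list alone (adjusted p = 0.021) and not over all genes (adjusted p = 0.077). Of the 20 genes from Bbr_1310 to Bbr_1329, 3 were at least 3-fold higher, 0 were at least 3-fold lower, and 15 stayed within 1.5-fold. In limma 4 of the 20 were higher and 1 lower over all genes, and 5 were higher and 2 lower adjusted over the list alone. The lower gene over all genes was Bbr_1325, at -0.80 ± 0.45. The median of the 20 was 0.10 ± 0.18, at percentile 98.2 of its matched random lists, and rested on array 2: it was 0.00097 on array 1 and 0.25 on array 2. These random lists also ignored gene order, so the percentile has the same limit.

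**Figure D1:**
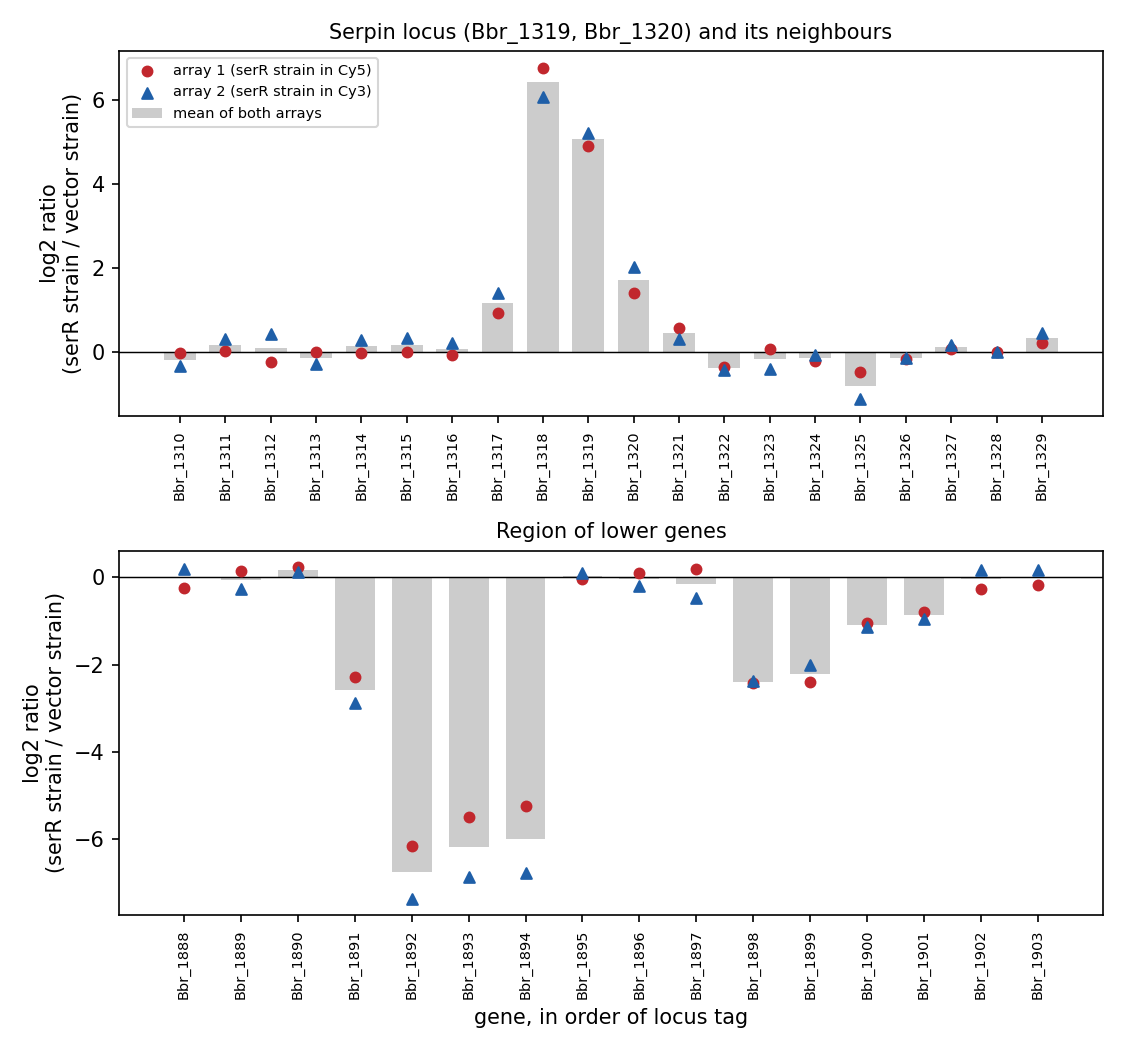
Log2 ratio of the serR strain over the vector strain for each gene in order of locus tag, for the serpin locus with its neighbours (top) and for the region of lower genes (bottom). Bars are the mean of both arrays and points are the single arrays (array 1 circles, array 2 triangles). Bbr_1318 and Bbr_1319 reach means of 6.42 and 5.07, and Bbr_1892 and Bbr_1893 reach -6.75 and -6.18. Genes such as Bbr_1317, Bbr_1319, Bbr_1320 and Bbr_1892 were not well above background in the dimmer strain, so their bars are measured values and not bounds.

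Over all 1843 genes, 8 were at least 3-fold higher in the serR strain and 7 at least 3-fold lower. The 8 higher genes were Bbr_1318, Bbr_1319 and Bbr_1320, Bbr_1464 and Bbr_0249, and 3 members of gene runs that were higher on array 2 alone. Bbr_1464 was 4.37-fold higher (log2 2.13 ± 0.09) and was well above background in both strains on both arrays. Bbr_0249 was 3.73-fold higher (log2 1.90 ± 0.18) and in the vector strain well above background on 1 of the 2 arrays. Both passed limma, with adjusted p of 1.3e-05 and 3.4e-05, and without background correction Bbr_0249 gave a log2 ratio of 1.49, under 3-fold. With Bbr_1318 and Bbr_1319, they were the 4 genes at least 3-fold higher on each array taken alone.

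Of the 7 genes at least 3-fold lower, 6 lay in 1 region. Bbr_1892 gave a log2 ratio of -6.75 ± 0.86 (adjusted p = 1.0e-06, limma). It was not well above background in the serR strain on either array. Its bound, on the mean of both arrays, came to 76.8-fold lower than in the vector strain (log2 6.26). That bound holds for this processing only and is no limit for each array. Array 1 alone gave a log2 ratio of -6.15, and without background correction the mean was -5.82. Bbr_1893 gave a log2 ratio of -6.18 ± 0.96 (adjusted p = 3.4e-06, limma). Its serR signal was well above background on array 2 and not on array 1, and stayed close to that of the negative controls, so no fold is given. The region spanned Bbr_1891 to Bbr_1901. The 4 consecutive genes from Bbr_1891 to Bbr_1894 were all at least 3-fold lower on the measured ratio. The 4 from Bbr_1898 to Bbr_1901 ranged from -2.40 to -0.87, and all 8 passed limma. Between them, Bbr_1895, Bbr_1896 and Bbr_1897 gave 0.04, -0.04 and -0.14, with signals at or near the level of the negative controls in both strains. The remaining gene past the 3-fold rule, Bbr_0925, lay outside this region, at -1.96 ± 0.23 (adjusted p = 3.4e-05, limma), well above background in both strains on both arrays. All 7 were at least 3-fold lower on each array taken alone.

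The 3 other higher genes belonged to runs that differed between the arrays. The genes from Bbr_0106 to Bbr_0109 had log2 ratios of 0.12 to 0.44 on array 1 and of 2.60 to 3.91 on array 2. Those from Bbr_1655 to Bbr_1658 ran from -0.15 to 0.11 on array 1 and from 3.61 to 4.67 on array 2. Bbr_1656 was well above background in the serR strain on 1 of the 2 arrays and in the vector strain on neither. Its bound came to 1.75-fold, but includes the serR level of array 1, which was not well above background, so it is no firm lower limit. Bbr_1656 did not pass limma (adjusted p = 0.13). The opposite was seen from Bbr_1843 to Bbr_1845, which ran from 0.31 to 0.73 on array 1 and from -3.03 to -2.26 on array 2. For such genes the difference between the strains was not larger than the spread between the arrays. In 6 of the 15 genes past the 3-fold rule one strain was not well above background on either array, and in 2 of the 6, Bbr_1319 and Bbr_1892, the bound itself exceeded 3-fold.

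**Figure D2:**
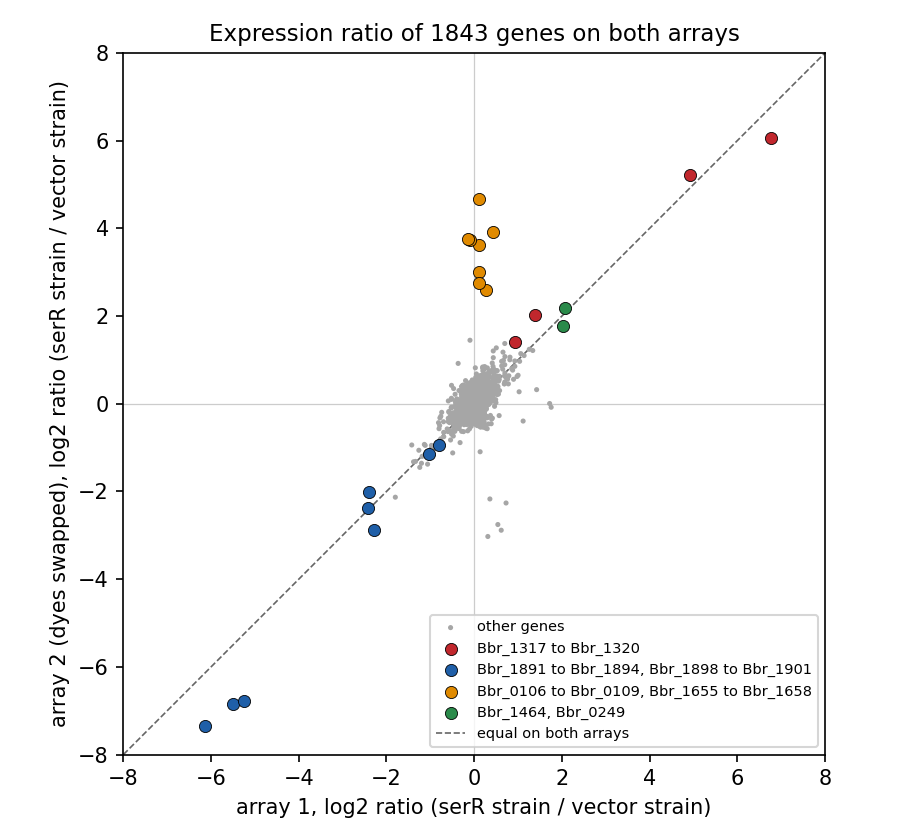
Log2 ratio of the serR strain over the vector strain on array 1 (horizontal axis) and array 2 (vertical axis, dyes swapped) for 1843 genes, 1 point per gene; the dashed line marks equal ratios. The genes from Bbr_1317 to Bbr_1320 and Bbr_1464 and Bbr_0249 lie near the line at the upper right, and the lower genes of Bbr_1891 to Bbr_1901 near it at the lower left. The 8 genes of Bbr_0106 to Bbr_0109 and Bbr_1655 to Bbr_1658 lie near 0 on array 1 and at 2.60 to 4.67 on array 2.

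On the mean of both arrays, 94.5% of all genes stayed within 1.5-fold. In 436 genes neither strain was well above background on either array, and such genes have little room to show a change. Of the 479 genes well above background in both strains on both arrays, 91.6% stayed within 1.5-fold. The exopolysaccharide cluster makes the capsule-like surface polysaccharide of this strain. None of its 40 measured genes, Bbr_0430 to Bbr_0475, went beyond 1.5-fold, with log2 ratios from -0.38 to 0.45, and 0 passed limma either over all genes or adjusted over the list alone. Only 13 of the 40 were well above background in both strains on at least 1 array each, and 16 were so in neither strain, so a change in most of the cluster could not have been measured in full. Its median of -0.02 was at percentile 37.7 of matched random lists.

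In limma over both arrays, 120 genes passed an adjusted p of 0.05, 68 higher and 52 lower, and 360 had an unadjusted p under that threshold. With the deposited processed ratios limma called 0 genes, with 260 at an unadjusted p under that threshold, while the methods' t-test called 22 with its ratio threshold and 51 after Benjamini-Hochberg. In limma the prior degrees of freedom, the weight of the variance shared across genes, were 0.48 there and 7.24 with the raw intensities. So low a weight makes the test weak. Of the 120 genes called from the raw intensities, 34 differed by at least 2-fold and 12 met the 3-fold rule. On those intensities the methods' t-test with its ratio threshold called 12 genes, 5 higher and 7 lower. Genes are not independent replicates. Across them, the ratios of the arrays correlated with a Pearson r of 0.71 and a Spearman rho of 0.42 after the dye swap had been turned. A positive r after turning is what a swap of the dyes requires. The r before turning, -0.71, is by construction the same value with the other sign and is no second check. The r of 0.71 depends on few genes. It was 0.44 without Bbr_1317 to Bbr_1320, Bbr_1464, Bbr_0249 and Bbr_1891 to Bbr_1899, and 0.82 without the genes that differed between the arrays. The first set was picked largely for large ratios on both arrays and the second for disagreement between them. The direction of both shifts follows from that choice, and only their size is a result. Without array 1 the 3-fold rule gave 13 higher and 12 lower genes, and without array 2 it gave 6 and 7. Without background correction it gave 4 and 6, and with the deposited processed ratios 14 and 19. Over 8 alternative processings the log2 ratio ran from 5.41 to 7.65 for Bbr_1318, from 3.95 to 6.90 for Bbr_1319 and from -8.83 to -5.82 for Bbr_1892.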

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

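The array holds 45 features with no locus tag, which the comparisons of tagged genes do not use. Of these, 3 gave a signal well above background on every spot, in both strains and on both arrays. tRNA-Gln had a mean log2 ratio of the serR strain over the vector strain of -0.77 ± 0.05 (n = 2 arrays), with -0.80 on array 1 and -0.73 on array 2. tRNA-Glu had a mean of -0.65 ± 0.42, with -0.35 and -0.94. The 16S rRNA probe had a mean of -0.57 ± 0.997, with 0.13 on array 1 and -1.28 on array 2, so its arrays disagree in sign. None of the 16 plasmid and insertion-sequence features, and none of the 7 spike-in features, had a spot well above background. By name, none of these features belongs to pNZ44, the plasmid that both strains carried, so they say nothing about its signal.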

How the results depend on the processing

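Tests without the array-specific genes and without the genes named one by one were added after the data had been seen. The 3-fold rule gave 4 higher genes without background correction, 4 when each array had to pass alone, 18 at 2-fold and 14 with either form of the deposited ratios. For lower genes the counts were 22 at 2-fold and 19 with either form of the deposited ratios. With probes well above background in every channel, 416 genes were left, and 1 higher and 1 lower were called, since 2 of the 15 called genes remained. Of the 33 genes called with the deposited ratios, 13 were among those 15. Single arrays gave 6 to 13 higher and 7 to 12 lower genes. Leaving out the 13 genes that differed between the arrays gave 5 higher and 7 lower. limma called 208 genes without background correction, 59 at offset 16, 73 with medians over probes, 39 with only probes well above background, and 251 with an intensity trend. The methods' t-test called 12 with its ratio threshold and 67 after Benjamini-Hochberg. With the deposited ratios limma called 0, with 260 at an unadjusted p under 0.05, while the methods' t-test called 22 with its ratio threshold and 51 after Benjamini-Hochberg; 279 genes have ratios of exactly 0 on both arrays there. The median of the serpin locus was 2.44 without background correction and 4.59 with either form of the deposited ratios, and single arrays gave 3.15 to 3.63. The median of the exopolysaccharide cluster was -0.12 with median centring and -0.030 to 0.038 on single arrays. The r between the arrays was 0.53 with only probes well above background, 0.82 without the 13 genes and 0.44 without Bbr_1317 to Bbr_1320, Bbr_1464, Bbr_0249 and Bbr_1891 to Bbr_1899. The direction of the shifts to 0.82 and 0.44 follows from the choice of genes, by disagreement between the arrays or largely by large ratios. Apart from this and the effect of fewer genes, the cause was not tested. Signal over background limits the serpin genes: without the dim probes neither they nor Bbr_1892 could be measured. Of the other values, 52 for counts, medians and correlations stayed within the margin set for them, and of 81 values for 8 single genes (Bbr_1317 to Bbr_1320, Bbr_1892, Bbr_1893, and Bbr_1464 and Bbr_0249, the last pair singled out after their values were seen) 59 stayed within 1 SD, 22 moved further and 0 turned sign. The 59 include values that could not have moved further. With 2 arrays, each array alone always lies within 1 SD of their mean. Aquantile scaling leaves the ratios unchanged, which also holds for its values among the 52. Neither setting is evidence of stability. No paired analysis was possible because there is 1 group of ratios.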

Other observations

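The tests of dye bias, of the processing of the lower genes, of runs of neighbouring genes and of signals against the brightest negative control were chosen after the result was seen, and that of spot noise after the pattern was seen and before its own value.

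Smaller differences also came in blocks of neighbouring genes. The 7 genes from Bbr_0323 to Bbr_0329 were higher, with a median log2 ratio of 0.73, as were the 4 from Bbr_1416 to Bbr_1419 at 0.82 and the 3 from Bbr_1433 to Bbr_1435 at 0.79. The 3 genes from Bbr_1558 to Bbr_1560 were lower at -1.10 and the 3 from Bbr_0939 to Bbr_0941 at -1.03. All 20 genes of these blocks passed limma, and none reached 3-fold. The blocks were picked from these same ratios, as runs beyond 1.5-fold with one sign on both arrays and no 3-fold gene. Neither result is therefore independent support for them. The methods' t-test after Benjamini-Hochberg passed 11 of the 20 and none of the 7 from Bbr_0323 to Bbr_0329 (adjusted p from 0.27 to 0.51).

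Neighbouring genes changed together more often than their number gives by chance. Of 93 genes beyond 1.5-fold with the same sign on both arrays, 36 lay in 9 runs of at least 3 consecutive tags with one direction, 5 higher and 4 lower. In 10000 permuted gene orders the number of runs reached at most 2 (permutation p = 0.0001, the smallest they can give). This is consistent with shared transcripts, which these data do not show directly, and 1 of the 9 runs, Bbr_0106 to Bbr_0109, differed between the arrays.

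The genes whose ratio differed between the arrays may reflect RNA that was not the same on both. Each array lay at least 1 log2 unit from the mean of both in 13 genes, 8 of them higher and 5 lower on array 2. Noise between spots is argued against, as the SD between the spots of a gene on array 2 was 0.099 of the size of its log2 ratio in the median gene and at most 0.43. A bias of the green dye would move the vector strain's level between the arrays by as much as that deviation, a share of 1, and the median share was 0.072 with a maximum of 0.28. In the 8 genes higher on array 2 the vector strain's levels were only 7.22 to 8.51 log2 units. So little signal leaves no level for a dye bias to move, and the share cannot decide there. The 5 lower genes, at vector levels of 11.3 to 14.5, can show it. From Bbr_1843 to Bbr_1845 the vector strain's level changed by a median of 0.25 and the serR strain's by -3.05, which argues against dye bias in these genes. In the 8 genes higher on array 2, the serR strain's level was 3.47 log2 units higher there while the vector strain's differed by -0.08; since the labels name no second culture, a different serR culture or extract cannot be told apart from another event in that sample.

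The lower genes from Bbr_1891 to Bbr_1901 could reflect lost DNA in the serR strain or a lower transcript level; no DNA was measured, so a biological explanation, such as an effect of serR on this region, was not tested. Loss of the whole run is argued against by 2 genes, Bbr_1900 and Bbr_1901, which stayed well above background in the serR strain on both arrays, at no less than 2.58 times the brightest negative control. The number set beforehand as evidence against such a loss was 3 genes, which was not reached, but a run lost as a whole leaves no gene with such a signal. Processing is argued against by the smallest drop of Bbr_1892 to Bbr_1894 in the 8 alternatives that measured them, a log2 ratio of -5.22. Loss of Bbr_1892 to Bbr_1894 alone stays open: 2 of the 3 were well above background in the serR strain on array 2, which had been set beforehand as evidence against a loss, but the signal of the 3 over the negative controls was at most 1.85% of the vector strain's on either array, an amount that light from the other dye could also give.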
